A study of Mus musculus with 6 samples.

How the data were processed

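RNA of 6 samples of CT26 cells, 3 with the empty vector and 3 with the shRNA against Sep15, was measured on Affymetrix Mouse430_2 arrays after TRIzol extraction and biotin labelling of cRNA, per the labels' protocols. The deposited table holds 1 log2 value per probe set and array, made with RMA (robust multi-array average: background correction, normalization between arrays and summary of the probes of a set), per the submitters' processing notes. The RMA version and any filter are not given in the sources used here. The values ran from 3.31 to 14.24 and were used as deposited. Because normalization between arrays sets their distributions alike, a change of total RNA per cell would not appear in them. RMA values have no detection call, and differences of dim probe sets are compressed toward 0.

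Groups were taken from the sample titles. The series states that the 3 arrays of a construct came from different mRNA samples, but not whether these came from separate transfections or cultures. The p-values therefore measure the spread between these samples, whatever its source, and with 1 hairpin construct they do not cover differences between constructs. The labels do not say whether the transfected cells were clones or pools.

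Of 45101 probe sets, 64 array controls were set aside and 45037 were tested. In the platform annotation 34945 of these had 1 gene symbol, 932 several and 9160 none; no gene was named from the latter 2 kinds. Symbols were updated by gene identifier through the RefSeq gene table of assembly GRCm38.p6, in which 34741 of the 34945 single-symbol probe sets were found. The arrays name no genome build, so that table served for names and for the order of neighbouring genes. A gene's value was that of its brightest single-symbol probe set over all 6 arrays, which gave 18193 genes, 9010 of them with several probe sets. In 60 genes probe sets were called in opposite directions, 46 of them changed genes. The background level, log2 6.02, was the 95th percentile of the means of 80 probe sets for olfactory and vomeronasal receptors, and 47.5% of probe sets lay above it. A gene with both group means under it is called near background; this held for 7062 genes, 181 of them changed.

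Each probe set was fitted with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, with the group as the only term. The two-sided moderated test was adjusted by the Benjamini-Hochberg method over 45037 probe sets, at a threshold of 0.05. Log2 differences are shSep15 minus control. The 19 gene lists, the test and the alternatives were fixed before the data were examined: selenoproteins, selenocysteine insertion, folding in the endoplasmic reticulum, antioxidant genes, G1/S and replication, G2 and mitosis, p53 targets and kinase inhibitors, interferon-stimulated genes, antigen presentation, epithelial genes, mesenchymal and matrix genes, proteolysis and invasion, Wnt targets, hypoxia and glycolysis, NF-κB and chemokines, cholesterol synthesis, immediate early genes, leukocyte markers and endothelial markers. Each list was compared with all other genes by camera of limma with a preset correlation of 0.01, adjusted over the 19 lists. With an estimated correlation 0 of the 19 passed (lowest adjusted p = 0.204), and 2 had an unadjusted p under 0.05. The fry test asks whether a list's genes move on balance one way, or, in its mixed form, in either direction, and compares them with no other genes.

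The genes named in the text were chosen by a rule fixed beforehand. It took the targeted gene with all its probe sets, Uggt1 and Uggt2, and up to 4 members of each list with the largest absolute difference among those past the threshold. It also took the 12 rises and 12 falls with the largest differences among genes past the threshold whose groups did not overlap and whose higher mean exceeded the background level, leaving out uncharacterised transcripts; 1 of the 12 falls is not reported here. Genes named beyond the rule are marked where they stand.

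Gene order was tested on 10857 genes above background on chromosomes 1 to 19 and X, with differences limited to a log2 of 2 in either direction for the correlations between genes. Medians per chromosome and correlations between genes 1 to 50 places apart were compared with 1000 shuffles of the genes, and running medians of 25 genes with 100 shuffles. These tests and the lists named in the last part of the closing section were chosen after seeing the data. So were the counts and list tests without whole chromosomes.

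On simulated data with the 45037 probe sets of this comparison, limma recovered 25.4% of the probe sets changed by a log2 of 0.5. It recovered 73.1% of those changed by 1 and 97.0% of those changed by 2, and 0.8% of its calls were false. The simulation changed far fewer probe sets than the 8722 called in the data, with noise independent between probe sets. The adjusted threshold depends on the share changed, so these percentages do not carry over to the data. In simulated lists a shift of 0.5 was called and 0 of 18 unshifted lists were. The simulated genes varied independently, whereas the estimated correlation was 0.162 in the G1/S list and 0.713 in the interferon list. The simulation therefore does not show how often camera with the preset correlation calls unshifted lists of correlated genes.

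The alternatives were a further quantile normalization, a shift of each array to the same median, eBayes without the trend or with robust settings, array weights, the replicate number as a block, probe sets above background, the mean of a gene's probe sets, an adjusted p under 0.01, treat against a 1.2-fold change, camera with an estimated correlation, fry, and each array left out in turn. Figures were drawn with matplotlib 3.10.9. Protein levels, cell growth and DNA copy number were not analysed here.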

Results

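Gene expression was measured in CT26 cells, a transplantable colon carcinoma line of BALB/c mice. One group of 3 samples came from cells transfected with the empty vector pU6-m3, and is called control here. The other group of 3 samples, called shSep15, came from cells transfected with the same vector carrying a short hairpin RNA against Sep15, the 15 kDa selenoprotein. The hairpin held a 19-nucleotide stretch of the mouse Sep15 cDNA (acagaagagttccatttaa), which was not placed on a genome here. Each sample was hybridised to 1 Affymetrix Mouse430_2 array. The median log2 value of an array lay between 5.83 and 5.87. Across probe sets, the mean correlation of an array with the other arrays of its group was 0.993 to 0.995, and with the arrays of the other group 0.977 to 0.979. Some array controls stood apart on single arrays. The 3′ probe set for 18S ribosomal RNA read 8.31 on control 3, against 6.01 and 6.33 on the other control arrays and 6.25 to 6.53 on the shSep15 arrays, and the 5′ probe set 6.59, against 4.77 and 4.88 and 4.77 to 5.43. The BioB spike-in averaged 7.33 on control 1 and 7.96 to 8.53 on the other arrays. Precision is limited by the 3 arrays per group.

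The comparison asked which transcripts differed in colon carcinoma cells once Sep15 was knocked down. Selenof, the current symbol of Sep15, encodes a selenoprotein of the endoplasmic reticulum with a thioredoxin-like fold. Its brighter probe set read 12.40 ± 0.05 (log2, SD, n = 3) in control cells and 9.48 ± 0.13 (SD, n = 3) in shSep15 cells. The log2 difference of −2.92 (SE 0.08, limma adjusted p = 2.43e-07) left 13.2% of the control signal, and every shSep15 array lay below every control array. The other probe set of the gene read 4.71 in control and 4.70 in shSep15 cells. That is under the background level of 6.02, so it gives no reading of the knockdown. Of the glucosyltransferases that bind the Sep15 protein and test the folding of glycoproteins, Uggt1 was higher on its brightest probe set (log2 0.55, SE 0.10, limma adjusted p = 0.00307). Its 2 other probe sets above background were not called the same way, and the mean of its probe sets gave 0.23 (limma adjusted p = 0.0584). Uggt2 was near background in both groups (log2 −0.07, limma adjusted p = 0.723).

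**Figure D1:**
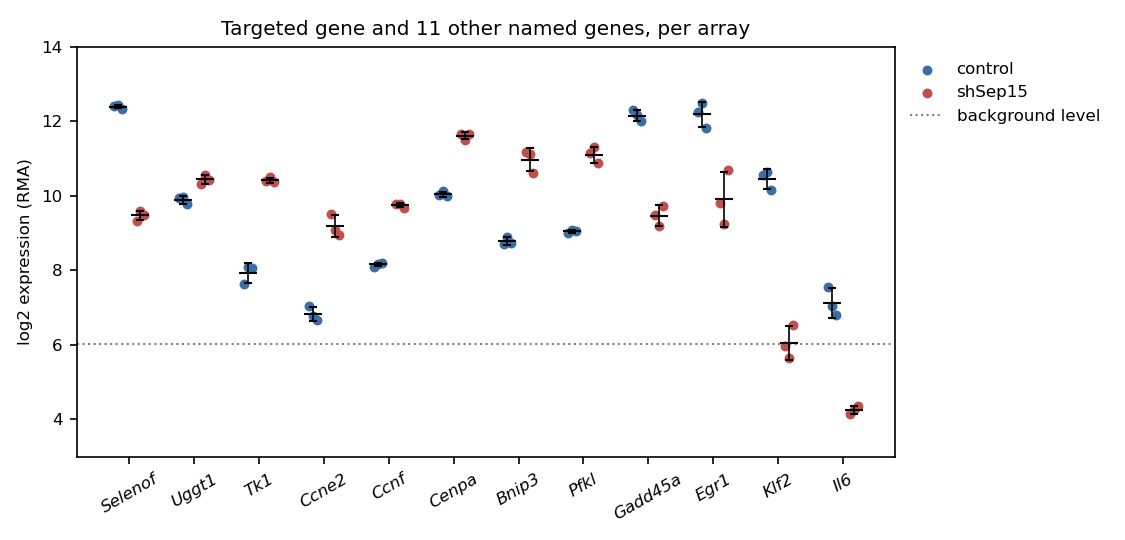
Log2 expression (RMA) of Selenof and 11 other named genes on each array, with points for the 3 control arrays and the 3 shSep15 arrays, horizontal bars for group means and whiskers for the SD; the dotted line is the background level of 6.02. Selenof went from a mean of 12.40 to 9.48, and in each gene shown the arrays of one group lie apart from those of the other.

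Many genes separated the groups, with rises and falls in near balance. Of 18193 genes, 2220 were higher and 2323 lower in shSep15 cells (limma, adjusted p under 0.05), which is 25% of the genes. Among the genes changed, 424 were at least 2-fold higher and 562 at least 2-fold lower, and the largest changes were mostly losses: 6 genes were at least 8-fold higher and 29 at least 8-fold lower. The median absolute log2 difference of a changed gene was 0.64. At the level of probe sets, 8722 of 45037 changed, 4372 higher and 4350 lower (limma).

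Of the 12 genes with the greatest rises, 10 had control means under the background level; the others were Elovl6 and Id3. For these 10 the difference was taken against signal not above background, so its size and rank are not exact. Tmem47, a membrane protein of cell junctions, rose by 4.29 (log2, SE 0.19, limma adjusted p = 2.15e-06), from 3.86 to 8.15. Morc4 rose by 3.77 and Ccnb1ip1, a ubiquitin ligase with a role in meiotic recombination, by 3.76. Elovl6, an elongase of long-chain fatty acids, rose by 3.10 from a control level of 7.87, and its 2 other probe sets above background rose as well. Also among the 12 were Myoz2 (3.23), Tyw3 (2.91), Fstl1 (2.83), Atp8a1 (2.74), the water channel Aqp1 (2.66), the guanylate-binding protein Gbp7 (2.66) and Id3, an inhibitor of basic helix-loop-helix factors (2.56). Eif4g3 rose by 3.84 on its brightest probe set, whereas its 1 other probe set above background was not called the same way.

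The genes of the 12 greatest falls were clearly expressed in control cells, with means of 9.75 to 13.07, and had means of 4.97 to 9.27 in shSep15 cells, the highest being that of Car6. The shSep15 means of Mamdc2, Dppa2, Nefl, Lcn2 and Slit3 were under the background level, so the sizes and ranks of these falls are not exact. Lrrn4cl fell from 12.06 to 6.26 (log2, SE 0.13, limma adjusted p = 1.19e-07), a 55.9-fold difference. Mamdc2 fell by 5.46 and Dppa2, a factor of germ cells and early embryos, by 5.26. Nefl, the light chain of neurofilaments, fell by 4.93, and the actin-binding protein Avil by 4.90. The transcription factor Klf2 fell by 4.40, Dynap by 4.04, the adhesion protein Cdsn by 3.93, the siderophore-binding protein Lcn2 by 3.92, the guidance ligand Slit3 by 3.84 and the secreted carbonic anhydrase Car6, from 13.07 to 9.27. For these 12 the limma adjusted p was at most 1.73e-05. That every shSep15 array lay below every control array follows from the rule that chose them.

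**Figure D2:**
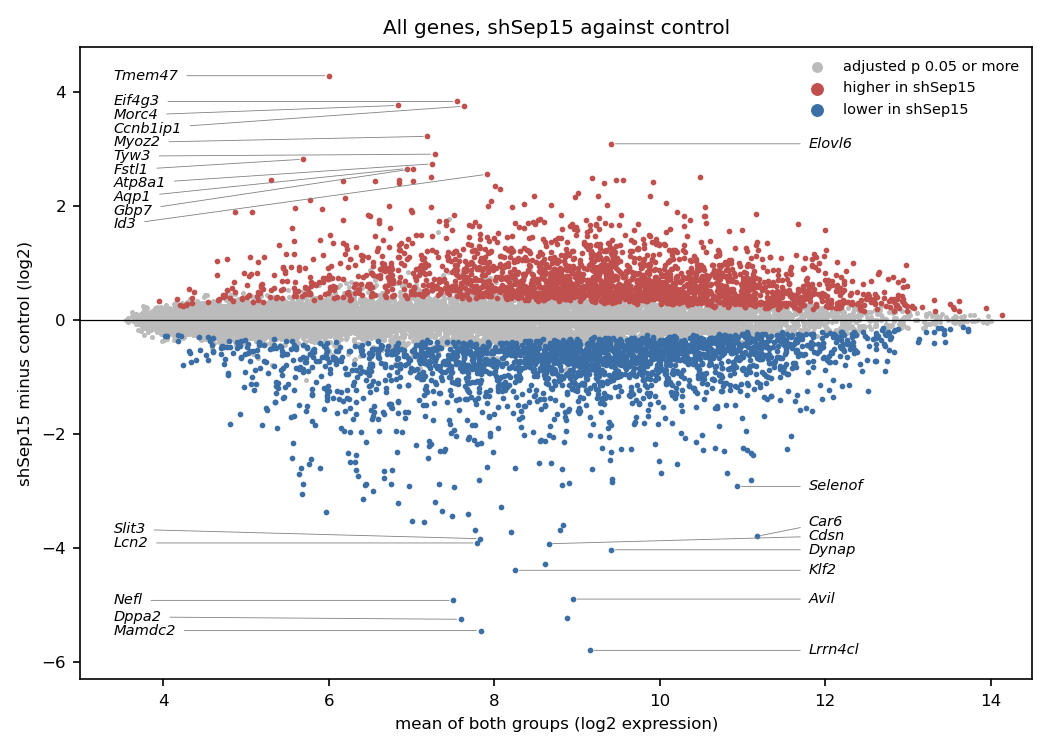
Each point is 1 of 18193 genes: the horizontal axis is the mean log2 expression of both groups, the vertical axis the log2 difference of shSep15 minus control. The 2220 red genes were higher and the 2323 blue genes lower (limma, adjusted p under 0.05); the labels name Selenof and the genes of the greatest rises and falls that the text names, with Tmem47 highest at 4.29 and Lrrn4cl lowest.

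Genes of DNA replication and of mitosis rose together, and these were the widest changes among the fixed gene lists. Of 33 measured genes of the G1/S transition and replication, 28 rose and 0 fell, with 29 past the threshold when adjusted over the list alone; the median log2 difference was 1.03. Thymidine kinase Tk1 rose by 2.49 (SE 0.14, limma adjusted p = 5.92e-06), cyclin Ccne2 by 2.36, the origin licensing factor Cdc6 by 2.17 and the helicase subunit Gins2 by 1.84. The 5 members not past the threshold were Rfc4, Pcna, Mcm2, E2f1 and Cdc25a, singled out after their values were seen. Of 34 measured G2 and mitosis genes, 30 rose and 1, Cdc25c, singled out after its value was seen, fell (log2 −0.51), with 32 past the threshold when adjusted over the list alone and a median of 0.87. Ccnf rose by 1.59, the centromeric histone Cenpa by 1.57, the kinesin Cenpe by 1.49 and the kinetochore protein Ndc80 by 1.48. The 1 other probe set of Cenpa above background was not called the same way. Both lists were higher by camera with a preset correlation (adjusted p = 6.39e-17 and 1.04e-16); adjusted p = 0.204 for each with an estimated correlation. Without chromosomes 3, 4, 17, 18 and X, 22 genes of each list still rose and 0 fell.

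Glycolytic and hypoxia-inducible genes mostly rose. Of 27 measured, 16 rose and 3 fell, 19 were past the threshold when adjusted over the list alone, and the median was 0.48. Bnip3, a mitophagy receptor, rose by 2.19 (SE 0.15, limma adjusted p = 1.81e-05), the phosphofructokinase subunit Pfkl by 2.06 and the pyruvate dehydrogenase kinase Pdk1 by 1.43. The list was higher by camera (adjusted p = 0.000259; adjusted p = 0.416 with an estimated correlation). The 3 members that fell were the hypoxia-inducible genes Ndrg1 (−2.04) and Vegfa (−0.94) and the hexokinase Hk2 (−0.63), the latter 2 singled out after their values were seen.

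Immediate early genes, transcribed within minutes of growth factor or stress signals, mostly fell. Of 25 measured, 13 fell and 2 rose, Dusp1 and Srf, singled out after their values were seen; 17 were past the threshold when adjusted over the list alone, and the median was −0.77. Apart from Klf2, Egr1 fell by 2.28 (SE 0.32, limma adjusted p = 0.000899), the feedback inhibitor Spry4 by 1.83 and Klf4 by 1.55. The list was lower by camera (adjusted p = 0.000248, and adjusted p = 0.539 with an estimated correlation). Egr1 and Spry4 lie on chromosome 18, where most genes were lower. Without chromosomes 3, 4, 17, 18 and X, 10 members still fell and 0 rose, with a mean of −0.85, against −0.78 with all. Among p53 targets and inhibitors of cyclin-dependent kinases, 7 of 27 fell and 2 rose, 10 were past the threshold when adjusted over the list alone, and the median was −0.19. The growth arrest gene Gadd45a fell by 2.69 (SE 0.14, limma adjusted p = 4.09e-06), the pro-apoptotic Bbc3 by 1.84 and the kinase Plk2 by 1.39, while the kinase inhibitor Cdkn2c rose by 1.32. This list was lower by camera (adjusted p = 0.0407; adjusted p = 0.571 with an estimated correlation). The call was lost without control replicate 1 (camera adjusted p = 0.0657, mean −0.24) or without shSep15 replicate 2 (camera adjusted p = 0.0541, mean −0.26), and without chromosomes 3, 4, 17, 18 and X (camera adjusted p = 0.0508), where the mean of the fewer members was −0.38, against −0.28 with all.

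**Figure D3:**
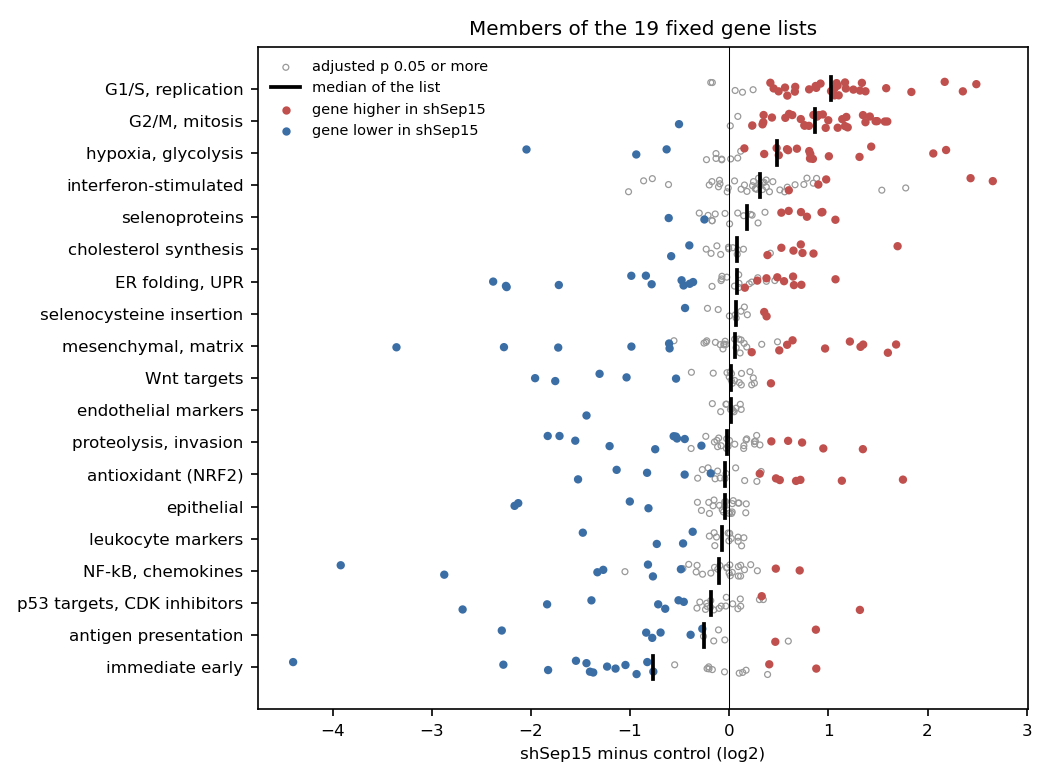
Log2 difference (shSep15 minus control) of each measured member of the 19 fixed gene lists, sorted by list median (black bars); filled points passed limma's adjusted p of 0.05 and open points did not. The list medians run from 1.03 for G1/S and replication to −0.77 for immediate early genes.

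Other selenoproteins changed in both directions, more of them upward. Of 22 measured besides Selenof, 7 rose and 2 fell, 12 were past the threshold when adjusted over the list alone, and the median was 0.18. The selenium carrier Selenop, under the background level in control cells so that its size and rank are not exact, rose by 1.07 (SE 0.19, limma adjusted p = 0.00385), the cytosolic glutathione peroxidase Gpx1 by 0.94, Selenoh by 0.93 and Selenot by 0.78; of the 2 other probe sets of Selenot above background, 1 was called the same way. Gpx4 (−0.25) and Selenoo (−0.61) fell, both singled out after their values were seen. The list was not past the threshold by camera (adjusted p = 0.0800). Among 11 factors that make or insert selenocysteine, 2 rose and 1 fell, 3 were past the threshold when adjusted over the list alone, and the median was 0.07 (camera adjusted p = 0.551). Sephs1 rose by 0.38 (limma adjusted p = 0.00954). Trnau1ap was higher by 0.35 and Secisbp2l lower by 0.45, at limma adjusted p = 0.0374 and 0.0469. The call of Trnau1ap ended without any 1 of control 1, 2 and 3 and shSep15 1 and 3 (limma adjusted p from 0.0524 to 0.129), that of Secisbp2l without control 1 or 2 or shSep15 2 or 3 (0.131 to 0.169). Both calls also ended when the arrays were shifted to the same median (0.0557 and 0.0573), that of Trnau1ap with the replicate block (0.0643) and that of Secisbp2l without the eBayes trend (0.0518).

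Genes of protein folding in the endoplasmic reticulum, the compartment of the Sep15 protein, moved apart. Of 34 measured, 9 rose and 11 fell, and 24 were past the threshold when adjusted over the list alone. The members with the greatest changes fell: Ppp1r15a by 2.38 (SE 0.08, limma adjusted p = 5.76e-07), as did Trib3 (−2.25), Ddit3 (−2.24) and the oxidoreductase Ero1a (−1.72). The first 3 are known as stress-induced targets of the transcription factor Atf4. The 1 other probe set of Ddit3 above background was not called the same way. The chaperone Hspa5 fell by 0.40, whereas its cofactor Sdf2l1 rose by 1.07, Creld2 by 0.73 and Calr by 0.38, genes singled out after their values were seen. The median was 0.08 and the mean −0.19, and camera's direction was down (adjusted p = 0.551). Among 24 thiol and quinone antioxidant genes, 7 rose and 5 fell, and 13 were past the threshold when adjusted over the list alone. The glutamate-cysteine ligase subunit Gclm rose by 1.75 (SE 0.09, limma adjusted p = 4.09e-06) and Pgd of the pentose phosphate pathway by 1.14, while the transporter Abcc4 fell by 1.52 and the haem oxygenase Hmox1 by 1.14. The median of the 24 antioxidant genes was −0.04, their mean 0.04 and camera's direction up (adjusted p = 0.676). Gclm and Pgd lie on chromosomes 3 and 4; without chromosomes 3, 4, 17, 18 and X, 3 members rose and 4 fell, the mean was −0.12 and camera's direction turned down (adjusted p = 0.527).

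The interferon-stimulated genes were split by array. Of 45 measured, 5 rose over the 3 arrays and 0 fell, the same number when adjusted over the list alone, with a median of 0.31. Gbp7 rose by 2.66 (SE 0.46, limma adjusted p = 0.00305), Gbp2 by 2.43, Ifi47 by 0.98 and the kinase Eif2ak2 by 0.90. The list was higher by camera (adjusted p = 0.0483; adjusted p = 0.805 with an estimated correlation), and this rested on shSep15 replicate 3. Over the 39 members above background, the median difference from the control mean was −0.18 on shSep15 1, 0.03 on shSep15 2 and 1.33 on shSep15 3. Usp18, singled out after its values were seen, read 6.77, 7.58 and 10.69 on these arrays and 6.17 to 6.79 on the control arrays. Without shSep15 replicate 3, 5 members were higher and 5 lower, the mean was −0.04 and camera's direction turned down (adjusted p = 0.692). The call also ended without any 1 of the control replicates (camera adjusted p from 0.0623 to 0.109), though the mean stayed at 0.38 to 0.42 against 0.40 with all arrays, and without chromosomes 3, 4, 17, 18 and X (0.126), where 2 members rose and the mean was 0.24. The call of Eif2ak2 ended without control replicate 2 (limma adjusted p = 0.0571). Gbp7 and Gbp2, both on chromosome 3, were raised on all 3 shSep15 arrays, from control means under the background level.

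**Figure D4:**
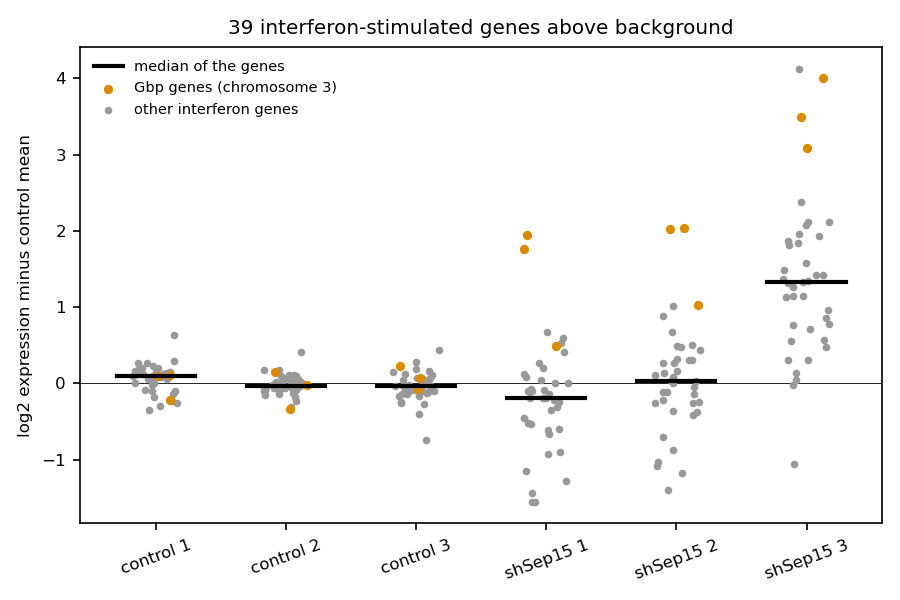
Log2 expression of 39 interferon-stimulated genes above background on each array, minus the gene's mean over the control arrays; black bars are medians over the genes and orange points the Gbp genes. The median on shSep15 3 was 1.33, against −0.18 and 0.03 on the other shSep15 arrays.

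Genes of antigen presentation by MHC class I fell more often than they rose: 6 of 13 fell and 2 rose, 9 were past the threshold when adjusted over the list alone, and the median was −0.26. Nlrc5, a transactivator of MHC class I genes, fell by 2.29 (SE 0.14, limma adjusted p = 1.13e-05), the checkpoint ligand Cd274 by 0.84 and the peptide trimming enzyme Erap1 by 0.78, while the proteasome activator Psme1 rose by 0.87. The list was not past the threshold by camera (adjusted p = 0.0800), but was without shSep15 replicate 3, the array with high interferon-stimulated genes (camera adjusted p = 0.0286). With all arrays and an estimated correlation, camera's adjusted p was 0.559. Among 32 NF-κB targets, cytokines and chemokines, 7 fell and 2 rose, 13 were past the threshold when adjusted over the list alone, and the median was −0.11. Besides Lcn2, the cytokine Il6 fell by 2.87 (SE 0.18, limma adjusted p = 1.15e-05), the NF-κB subunit Relb by 1.33 and the chemokine Ccl5 by 1.27. Lcn2 and Il6 were under the background level in shSep15 cells, so the sizes of their falls are not exact. This list lay close to the threshold (camera adjusted p = 0.0530), and passed it without control replicate 3 (0.0492) or without shSep15 replicate 3 (0.0403). Camera's adjusted p for it was 0.385 with all arrays and an estimated correlation.

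The epithelial and mesenchymal lists were not past camera's threshold. Of 28 epithelial junction and keratin genes, 18 were near background in both groups; 4 fell and 0 rose, 4 when adjusted over the list alone, and the median was −0.05 (camera adjusted p = 0.0800). The keratins Krt18 and Krt20 fell by 2.16 and 2.13 (SE 0.13 and 0.15, limma adjusted p = 9.66e-06 and 2.45e-05), the lectin Lgals4 by 1.00 and, near background, the protease inhibitor Spint1 by 0.81. Of 36 mesenchymal and matrix genes, 10 rose and 6 fell, 19 were past the threshold when adjusted over the list alone, and the median was 0.06 (camera adjusted p = 0.260). The receptor Pdgfrb fell by 3.36 (SE 0.27, limma adjusted p = 4.38e-05), the collagen Col3a1 by 2.27 and the proteoglycan Dcn by 1.72, while the matricellular protein Ccn1 rose by 1.68. Among 36 proteases, inhibitors and adhesion receptors of invasion, 10 fell and 5 rose, 18 were past the threshold when adjusted over the list alone, and the median was −0.03 (camera adjusted p = 0.388). The metalloproteinases Mmp13, near background, and Mmp19 fell by 1.83 and 1.71, the integrin Itgb4 by 1.55, and Adamts1 rose by 1.35 (SE 0.16, limma adjusted p = 0.000367). The shSep15 means of Krt18, Lgals4, Pdgfrb, Mmp19 and Itgb4 were under the background level, so the sizes of these falls are not exact.

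Of 22 Wnt target genes, 5 fell and 1 rose, 6 were past the threshold when adjusted over the list alone, and 11 were near background. The antagonist Dkk2 fell by 1.96 (SE 0.15, limma adjusted p = 3.25e-05), Ccn4 by 1.75, the receptor Fzd7 by 1.31 and Myc by 1.04. The value of Fzd7 is from its brightest probe set, and its 1 other probe set above background was not called the same way. Dkk2 was under the background level in shSep15 cells, so its size and rank are not exact. The median was 0.02, the mean −0.24 and camera's direction down (adjusted p = 0.478). Of 20 genes of cholesterol synthesis and uptake, 7 rose and 2 fell, 9 when adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.0824). The isomerase Idi1 rose by 1.70 (SE 0.16, limma adjusted p = 8.69e-05), Nsdhl by 0.85, Fdps by 0.74 and Cyp51 by 0.72.

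Markers of other cell types did not rise. Of 16 leukocyte markers, 0 rose and 4 fell, 4 when adjusted over the list alone, and 10 were near background, with a median of −0.07 (camera adjusted p = 0.181). Cd68 fell by 1.48 (limma adjusted p = 0.000297), Cd14 by 0.73, Lyz2 by 0.47 and, near background, Itgam by 0.37; the call of Lyz2 ended without control 2 (limma adjusted p = 0.0610) or shSep15 2 (0.0588), and that of Itgam without control 2, shSep15 2 or shSep15 3 (0.0645 to 0.0771). Of 12 endothelial markers, 1 fell, 1 when adjusted over the list alone, and 7 were near background; it was Vwf, by 1.45 (limma adjusted p = 0.00497). Cd68 and Vwf were under the background level in shSep15 cells, so the sizes of their falls are not exact. The median of the 12 endothelial markers was 0.02, their mean −0.11 and camera's direction down (adjusted p = 0.765).

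The changes were unevenly spread over the chromosomes. With 10857 genes above background placed in the order of the GRCm38.p6 gene table, the median log2 difference was 0.26 on chromosome 3, 0.16 on chromosome 4, 0.17 on chromosome 17 and −0.30 on chromosome 18. Each of these shifts exceeded the largest of any chromosome in 1000 shuffles of the genes (0.09; permutation p = 0.000999, the smallest they can give). Smaller shifts on chromosomes 1 (median −0.07), 12 (−0.06) and X (−0.05) had permutation p = 0.00599, 0.0240 and 0.0410. On chromosome 3, 69.1% of 541 genes were higher, and 87 of the 401 placed genes at least 2-fold higher lay there (Fisher's exact test, adjusted p = 6.92e-32 over 20 chromosomes). On chromosome 18, 25.8% of 260 genes were higher. Of the 510 placed genes at least 2-fold lower, 32 lay on chromosome 18 and 40 on X (Fisher's exact test, adjusted p = 5.38e-06 and 1.77e-07). Of the 12 greatest rises named above, 4 lay on chromosome 3: Myoz2, Elovl6, Tyw3 and Gbp7. In running medians of 25 neighbouring genes, the longest stretches beyond 100 shuffles were 66 genes from Ntng1 to Ube2d3 (median 0.86) and 66 genes from Cisd2 to Wls (0.70) on chromosome 3, 59 genes from Wdr55 to Smim3 on chromosome 18 (−0.61), and 83 genes from Syp to Rbmx2 on chromosome X (−0.69). Selenof lies on chromosome 3 among rising neighbours: of the 5 placed genes on either side, 8 rose and 1 fell past limma's threshold, with a median of 0.81. Without chromosomes 3, 4, 17, 18 and X, taken for their shifts beyond all shuffles or, for X, its run of neighbours, 236 genes were at least 2-fold higher and 435 at least 2-fold lower.

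**Figure D5:**
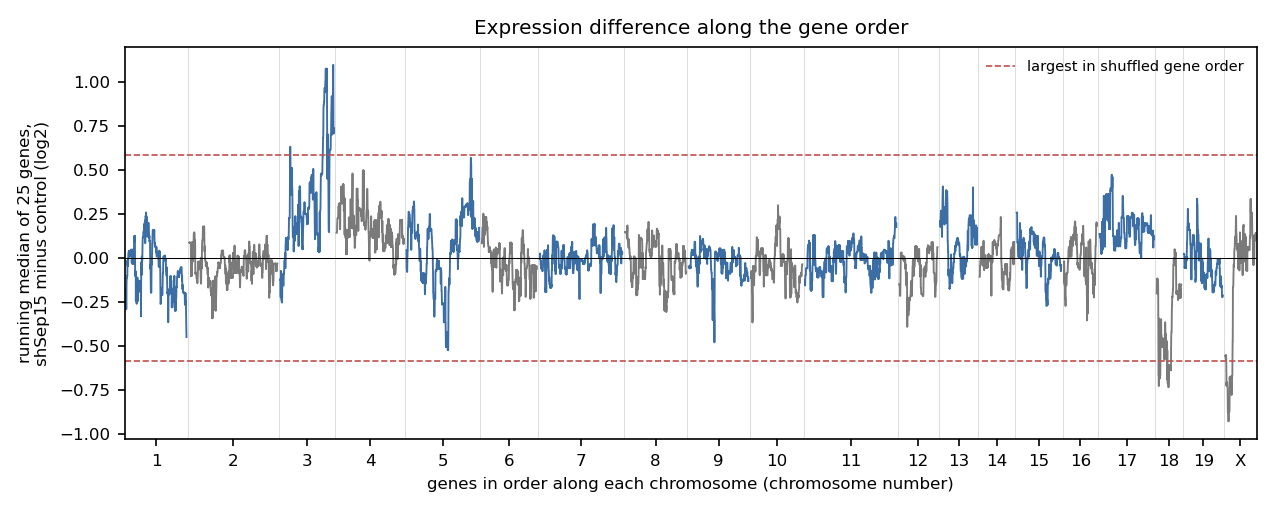
Running median of the log2 difference (shSep15 minus control) over 25 neighbouring genes above background, in gene order along chromosomes 1 to 19 and X; dashed lines mark the largest running median in 100 shuffles of the gene order (0.59 in size). Stretches of chromosome 3 lie above and stretches of chromosomes 18 and X below these lines.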

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

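Outside the compared genes lay the 10092 probe sets without a single gene symbol, of which 871 changed (limma), and the 64 control probe sets of the array. The tests of the latter were not adjusted together with the genes. Probe sets for beta-actin among them read higher in shSep15 cells than in control cells on every array: by 0.26 (log2) for the 3′ probe set, 0.29 for the 5′ probe set and 0.32 for the middle one (limma adjusted p = 0.00731, 0.0180 and 0.0102 over the control probe sets). The gene's own probe set, Actb, gave 0.20 (limma adjusted p = 0.0101). Other control probe sets read lower in shSep15 cells: 2 for pyruvate carboxylase, by 0.64 (3′) and 0.53 (middle), and 1 for a murine B1 repeat, by 0.17 (limma adjusted p = 0.00731, 0.0203 and 0.0230 over the control probe sets). No explanation was tested for these differences.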

How the results depend on the processing

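The counts and list tests without whole chromosomes were chosen after seeing the data, and all other alternatives were planned. Of 125 values of the knockdown and of counts under the alternatives, 118 stayed on their side of the threshold or within 1.5 times. So did 1299 of 1319 values of named genes and 288 of 323 list shifts. Most named genes were picked for large differences past the threshold, so their share follows in part from that rule. Of all 4543 changed genes, 2234 were called again under treat. For the lists, 18 shifts lost the threshold, 16 gained it and 1 reversed. Reversed means that the direction of the list test changed and the list passed in either setting. The genes that lost a call were Secisbp2l, Trnau1ap, Eif2ak2, Lyz2, Itgam and Uggt1, none with a change of sign. The counts fell by construction with stricter thresholds: at an adjusted p under 0.01, 1475 genes were higher, and under treat against a 1.2-fold change 1042 were higher and 1192 lower. Without chromosomes 3, 4, 17, 18 and X, 236 genes were at least 2-fold higher. The fit was unchanged there, and the genes on these chromosomes were only left out of the count. The number of lists past the threshold was 0 by camera with an estimated correlation, 15 by fry and 18 by fry in its mixed form. With the preset correlation camera gave 6, and only the correlation setting differed between its counts. The counts by fry answer another question, as fry compares a list with no other genes. The interferon list, 0.678 without shSep15 replicate 1, reversed to −0.044 without shSep15 replicate 3.

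Leaving out 1 array at a time gave 1697 to 1965 genes higher and 1800 to 2308 lower, 393 to 459 at least 2-fold higher and 518 to 633 at least 2-fold lower, 3306 to 3818 probe sets higher and 3256 to 4339 lower, 4 to 7 lists past camera's threshold, and a Selenof difference of −2.98 to −2.85. The mean of both Selenof probe sets, of which 1 lies at background, gave −1.47 by its construction. With 1 array left out, camera's adjusted p ran from 0.0179 to 0.0657 for the p53 list and from 0.000228 to 0.692 for the interferon list. With all arrays and an estimated correlation, camera's adjusted p was 0.571 and 0.805. The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.399, −0.201 and −0.055 across probe sets. The highest correlation across the groups was 0.442, between control 3 and shSep15 2. These arrays also had the largest 3′ minus 5′ log2 differences of the transferrin receptor control, 1.805 and 1.944, against 1.431 to 1.693 on the others. A technical factor shared by them was not tested. With the replicate block, 2246 genes were higher and 2345 lower, and 7 lists passed. With 1 array left out, 3443 to 3955 of the 4543 changed genes were called again. The median difference of all genes was 0.007, and 0.009 and −0.001 under the other scalings. The signal over background limits what can be seen of genes near background.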

Other observations

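The tests on chromosome order, on the array with high interferon genes (except that of leukocyte markers), on the cell cycle genes and on fatty acid oxidation were chosen after the results were seen. The 5 lists described first were chosen after the main results, and hold no member of the 19 fixed lists. The remaining tests were set before their values were seen. The genes named for the 5 lists were chosen after their values were seen.

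Target genes of Atf4, the transcription factor of the integrated stress response, fell beyond those in the fixed lists. Of 29 measured, 21 fell and 0 rose, with a median log2 difference of −0.469. The list was lower by camera (adjusted p = 6.55e-13 over 5 lists; adjusted p = 0.0319 with an estimated correlation). Examples are Cth of cysteine synthesis (−2.71), the mitochondrial folate enzyme Aldh1l2 (−2.02), the stress factor Nupr1 (−1.25), the tryptophanyl-tRNA synthetase Wars (−1.24) and asparagine synthetase Asns (−0.42); Cth fell to under the background level, so its size is not exact. Serine synthesis genes of the list, Phgdh (−0.07), Psat1 (−0.17) and Psph (−0.11), did not pass limma's threshold. Atf4 itself fell by 0.46. Lower activity of Atf4 may account for this, as a hypothesis; its activity was not measured apart from these transcripts.

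Genes of homologous recombination and replication fork repair rose: 21 of 25 rose and 1, Recql4, fell, with a median of 0.913 (camera adjusted p = 6.55e-13; adjusted p = 0.0319 with an estimated correlation). Rad54l rose by 2.00, Rad54b by 1.96, Clspn by 1.59, Brca1 by 1.51 and Chek1 by 1.22; the control mean of Rad54b was under the background level, so its rise is not exact. Many of these genes are transcribed in S phase, so the list is not independent of the cell cycle lists. The other added lists showed no common direction. Outputs of the ERK pathway beyond the immediate early genes had 3 members higher and 4 lower of 15 (median −0.177, camera adjusted p = 0.435); Dusp4 fell by 1.52 and Spred3 rose. Of 23 germ cell genes, 19 near background, 1 rose and 2 fell (median −0.002, camera adjusted p = 0.857). The fall of Dppa2 was shared by Dppa4 (−2.94) and by Taf7l (−2.28). Of 20 genes of fatty acid oxidation, 8 rose and 4 fell (median −0.009, camera adjusted p = 0.634).

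Runs of neighbouring genes on chromosomes 3, 18 and X shifted together. Genes 50 places apart still correlated (r = 0.05 across genes, highest of 1000 shuffles 0.035). This value was taken over all chromosomes, so shifts of whole chromosomes add to it. It cannot decide whether clusters of co-regulated neighbours made the runs. A difference in copy number of chromosome segments between the 2 cell populations may account for the runs, as a hypothesis. Over all chromosomes, genes 20 places apart correlated at 0.097 (highest shuffle 0.03). The value was 0.075 without chromosome 3 and 0.052 without chromosomes 3, 18 and X (highest shuffles 0.029 and 0.039). The correlation was thus not confined to the chromosomes with runs, and does not test the runs apart from other shifts. The knockdown itself cannot be told apart from a difference between cell populations, because the design has 1 shRNA construct and 1 empty vector. DNA was not analysed here.

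Interferon-stimulated genes were high on shSep15 replicate 3. The list's median deviation from the other arrays of the group was 1.381, with 37 of 39 genes above both other arrays. The largest median of 10000 random lists matched on mean level was 0.115. The list was examined because it was high there. Its genes also move together (estimated correlation 0.713), whereas random lists hold unrelated genes. The comparison therefore gives a size and no independent evidence. A gain of chromosome 3, where Gbp7 and Gbp2 lie, is argued against as the whole cause by the 36 members on other chromosomes. Their median was 1.367 (95% bootstrap interval 1.17 to 1.49). This interval and the next resample genes as if independent, and do not cover the spread between cultures. RNA from leukocytes is argued against as the whole cause by their 16 markers, 10 of them near background (median −0.066, interval −0.177 to 0.034, under the bound of 0.5 set for this test); Lyz2 read 6.69 on this array against 6.59 and 6.47, and Cd14, expressed in control cells too (9.33), read 8.35 against 8.82 and 8.63. An interferon response of that culture is consistent with these values, as a hypothesis, and no biological explanation from the design was tested, since the array shares its group with the other two.

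The rise of G1/S and G2/M genes was not confined to the shifted chromosomes, as the 52 genes elsewhere had a median of 0.875. Its 95% bootstrap interval, 0.666 to 1.06, resamples genes as if independent and does not cover the spread between cultures. These values cover where the cell cycle genes lie. They cannot decide whether the shifted chromosomes affected genes elsewhere. The rise did not rest on 1 outlying array, as the median of the 67 genes was at least 0.884 whichever array was left out. Density or growth state of the cultures at harvest stays open, since 0 labels record density, confluence or serum. The knockdown, this state and a difference between the cell populations cannot be told apart here.

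The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split alone, 1 of 10, gave 8722 changed probe sets and 4543 changed genes by limma, and the highest other split gave 0 of each. Every other split puts arrays of both groups on each side, so the difference between the groups widens the spread there. The 0 calls are therefore no measure of chance. For the gene lists 4 of the 10 splits gave as many past camera's threshold as the real split, with 6 in the real split and 7 in the highest other one. Each other split still holds part of the group difference, so these list counts are no chance level either.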
